A study of Mus musculus with 8 samples.

How the data were processed

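Ribosomal RNA-depleted total RNA from the livers of lean wild-type C57BL/6 mice was measured by sequencing in 8 libraries, 2 in each of 4 groups. The mice had received 0.1 OD of an adenovirus and were killed 1 week later, after 6 h without food. Mice of 3 months carried the control virus lacZ1 or a short hairpin RNA virus against Dnajb9, and mice of 4 months carried the control virus lacZ2 or a short hairpin RNA virus against Rictor. The labels do not say whether the control virus carried the lacZ gene or a hairpin against it. They do not say either whether the libraries of a group came from separate animals, so every p-value measures only the spread between these samples. Within each group the counts of the 2 libraries differed by more than counting error, with a chi-square per degree of freedom between 18.2 and 51.98.

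The deposited values were raw counts per gene symbol, 1 table per library, which the authors made with HTSeq on mouse genome build mm10 after trimming with cutadapt. Each table also held the classes of reads that HTSeq left unassigned. The aligner, the tool versions, the gene annotation and the strand setting were not given in the labels. A count can therefore include reads of antisense or overlapping transcripts. The tables listed 24062 gene entries, of which 27 carried a calendar date in place of a symbol. These were counted in the library totals and could not be assigned to a gene, and 2 of the date names each stood for 2 entries. For transcript length, GC content, position and shared sequence, 98.3% of the entries were matched to GENCODE release M21, 933 of them through an older symbol. A gene was called uncertain when 20% or more of its 50-base stretches also occurred in another gene, which held for 1461 of the tested genes.

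Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr with a minimum count of 10, which left 13767 genes to test and 10295 out. Library sizes were scaled by the trimmed mean of M values (TMM), and CPM values are TMM-normalised. A single design with 4 group means was fitted to all 8 libraries, with robust moderation, since 2 libraries per group leave 4 residual degrees of freedom in all. The common biological coefficient of variation was 0.209 and the median prior degrees of freedom were 9.07. The quasi-likelihood F test of edgeR was applied to 4 contrasts, namely shDnajb9 minus lacZ1, shRictor minus lacZ2, the difference between these, and lacZ2 minus lacZ1. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors are those of the log2 fold change unless marked as bootstrap, and n is 2 libraries per group. Groups of 2 allow no exact permutation test under 0.05 and no test of single libraries as outliers, so only model-based adjusted p-values are given.

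Genes were tested as 33 lists, 21 of pathways and 12 of cell type markers, with camera at a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists of a contrast. Camera with an estimated correlation and fry were run beside it. With an estimated correlation, camera rests on the 4 residual degrees of freedom and has little power here. Camera compares a list with the other genes, whereas fry asks whether the genes of a list move on balance in 1 direction. No list holds Dnajb9 or Rictor. Of the list entries, 40 were not tested, among them the globin genes and most pancreas markers.

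The groups, contrasts, tests, lists and the rule for named genes were fixed before the data were examined. The named genes are the 2 targets, a panel of 20 genes of mTOR complex 2, insulin signalling, gluconeogenesis, lipogenesis and endoplasmic reticulum stress, and, per knockdown, the 8 risers and 8 fallers with the smallest adjusted p. These needed an average log2 CPM of at least 1 and no overlap between the libraries of both groups, and clone-based or predicted names were left out. Up to 4 members with the smallest p of each called list, the 5 highest and 5 lowest of the called genes of the difference, and up to 5 genes called in both knockdowns in the same or opposite direction were added. Rn45s, Rpph1, Mpo, and genes named because few members of a list went against the rest were chosen after their values were seen. The results of some genes that this rule names are not reported. Pearson's r and Spearman's rho across genes are described without p-values, since genes are not independent replicates, and overlaps were tested with Fisher's exact test, one-sided.

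Alternatives fixed beforehand were RLE size factors, total count only, no filter, a stricter filter of 2 CPM in 2 libraries, non-robust moderation, leaving out the 10 most abundant genes, DESeq2 1.42.0, limma-voom, a fit to only the 4 libraries compared, a replicate block, a test against a 1.5-fold change, an adjusted p under 0.1, and leaving out each library in turn, where the lone library of a group is assumed to vary like the other groups. Added after the data were seen were a length and GC correction by smooth trends per library, a fit without 2 libraries that stood apart, a fit without genes that share sequence, and a crossed block. Tested on simulated data with 200 changed genes per knockdown, the procedure recovered 32.8% of 2-fold and 92.4% of 4-fold changes in the Dnajb9 contrast and 34.3% and 97.0% in the Rictor contrast. Of 97 and 103 calls, 14 and 13 were genes without a simulated change, so the share of false calls was above the nominal level there.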

Results

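Gene expression was measured in mouse liver after knockdown of Dnajb9, which encodes the endoplasmic reticulum co-chaperone ERdj4, or of Rictor, a subunit that defines mTOR complex 2. Each knockdown had its own control, lacZ1 for shDnajb9 and lacZ2 for shRictor, with 2 libraries in every group. The series sets out to relate a chaperone to nutrient sensing and energy metabolism by mTOR complex 2. Counts assigned to genes were 9791933 and 7830716 in lacZ1, 6426164 and 9606030 in shDnajb9, 6727294 and 10464225 in lacZ2, and 9255887 and 11383532 in shRictor, for replicates 1 and 2. With 2 libraries per group, the median standard error of a log2 fold change was 0.293 in the Dnajb9 contrast and 0.288 in the Rictor contrast.

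The libraries separated first into lacZ controls and libraries with a hairpin against Dnajb9 or Rictor. On the first principal component, with 63.3% of the variance, the 4 lacZ libraries lay between -61.32 and -39.89. The 4 libraries of shDnajb9 and shRictor lay between 27.95 and 74.99. The second component, with 16.8%, ran from -48.07 in shDnajb9 replicate 1 to 45.79 in shRictor replicate 2. Of all HTSeq counts, in genes and unassigned classes, the class without a unique alignment made up 41.3% and 41.97% in shDnajb9 against 22.88% and 24.88% in lacZ1. It made up 32.69% and 26.72% in shRictor against 24.59% and 24.23% in lacZ2. Among gene counts, Rn45s, the ribosomal RNA precursor, took 2.60% and Rpph1, the RNA of ribonuclease P, 4.26% in lacZ2 replicate 1. In shDnajb9 replicate 1 Rpph1 took 4.70%. These 2 libraries, shDnajb9 replicate 1 and lacZ2 replicate 1, were also left out together.

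The targeted transcripts were lower in their own knockdown but did not pass the test. Dnajb9 (chromosome 12, 44205559 to 44210326, minus strand) stood at 30.6 and 38.0 CPM in lacZ1 and at 22.0 and 20.3 CPM in shDnajb9, and at 40.4 and 38.8 CPM in lacZ2 and 61.1 and 43.8 CPM in shRictor. Its log2 fold change after its own knockdown was -0.70 (SE 0.247, adjusted p = 0.056, edgeR), lower in 2 of 2 libraries. With total count only the value was -1.12 (adjusted p = 0.0111), and after the length and GC correction it was -1.06 (adjusted p = 0.0016). Without the low-count filter it was -0.71 (adjusted p = 0.0484). Rictor (chromosome 15, 6708379 to 6800401, plus strand) stood at 65.4 and 68.8 CPM in lacZ1 and 33.3 and 63.4 CPM in shDnajb9. It was at 52.3 and 65.2 CPM in lacZ2 and at 40.1 and 42.0 CPM in shRictor, a log2 fold change of -0.52 (SE 0.281, adjusted p = 0.231). With total count only this was -0.92 (adjusted p = 0.0654). In the other knockdown, Rictor changed by -0.46 (adjusted p = 0.239) and Dnajb9 by 0.41 (adjusted p = 0.271). Between the contrasts Rictor differed by -0.06 (adjusted p = 0.97, edgeR) and Dnajb9 by 1.10 (adjusted p = 0.394). A lower Rictor level particular to the Rictor hairpin was thus neither shown nor excluded. Both shRictor libraries lay below both lacZ2 libraries, while in shDnajb9 the lower level rested mainly on replicate 1. Knockdown below names the hairpin delivered, not a shown loss of its target. The Rictor value in shDnajb9 was -1.01 (adjusted p = 0.017) without shDnajb9 replicate 2 and -0.08 without shDnajb9 replicate 1.

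**Figure D1:**
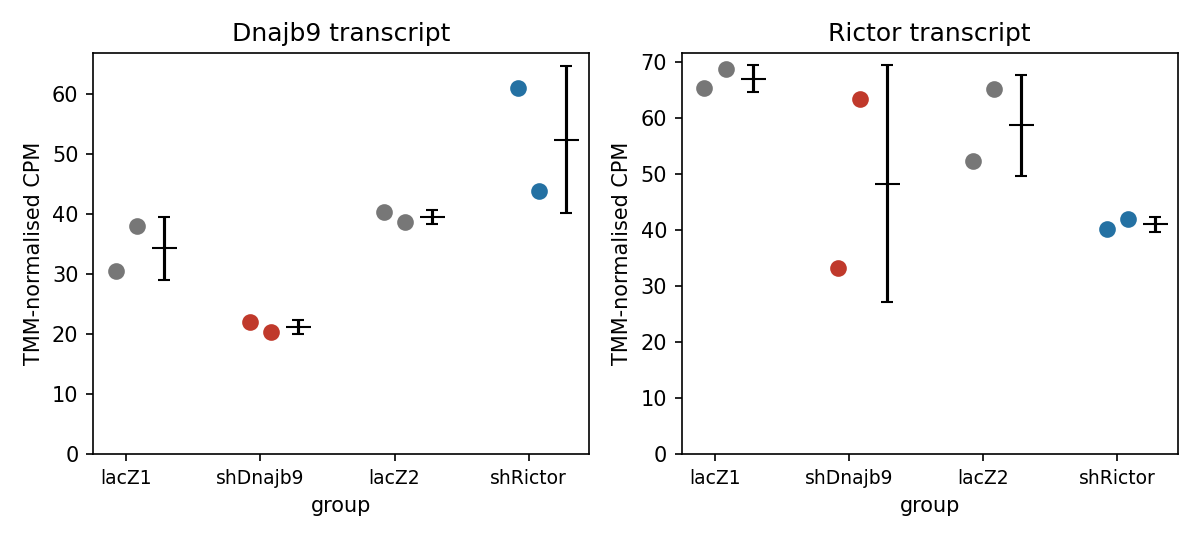
TMM-normalised CPM of Dnajb9 (left) and Rictor (right) in each group, with 1 point per library and, to its right, the mean with bars of 1 SD (n = 2). Dnajb9 was at 22.0 and 20.3 CPM in shDnajb9 against 30.6 and 38.0 in lacZ1, and Rictor at 40.1 and 42.0 CPM in shRictor against 52.3 and 65.2 in lacZ2.

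The comparison of shDnajb9 with lacZ1 asks which transcripts differ after delivery of the hairpin against Dnajb9. Most genes of the cell cycle fell, as did part of the p53 and NRF2 targets. Of cholesterol synthesis genes 16 of 26 rose, of growth hormone dependent genes 13 of 24, of gluconeogenesis genes 11 of 19 and of endoplasmic reticulum chaperones 14 of 40. None of these lists was called with an estimated correlation (adjusted p = 0.388, 0.388, 0.366 and 0.427). Of 13767 genes, 3325 were called, 1597 that rose and 1728 that fell, and 1114 and 1406 of these changed 2-fold or more. The largest risers among the named genes included Ppp1r3g, a subunit that directs protein phosphatase 1 to glycogen, which went from 1.29 ± 0.197 to 43.1 ± 1.96 CPM (SD, n = 2). This was 33.3-fold, or 5.06 on the log2 scale (SE 0.357, adjusted p = 1.81e-05). Slc22a7, an organic anion transporter, rose by 4.32 (SE 0.41, adjusted p = 6.07e-05), and Extl1, Sntg2, Acpp and Mpv17l rose by 3.18 to 3.79. Mup1 and Mup7, major urinary proteins, rose by 5.57 and 5.81, but 94.8% and 89.8% of their sequence is shared with other genes, so the member is uncertain. Among the fallers, Cbr3, a carbonyl reductase, fell by 5.26 and Ly6d by 4.58 on the log2 scale, and the mitotic genes Ckap2, Gtse1 and Ckap2l fell by 4.05, 3.96 and 3.66. Cox6b2 fell by 4.92 and Cyp2a4 by 5.80, and 38.8% of the Cyp2a4 sequence is shared.

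These counts rest on the scaling and on single libraries. With total count only, which moves the median log2 fold change of all genes from -0.05 to -0.464, 610 genes rose and 3354 fell. The number called was 988 without lacZ1 replicate 1, 2050 without lacZ1 replicate 2, 1365 without shDnajb9 replicate 1, 1678 without the 2 libraries that stood apart and 1314 against a 1.5-fold change. All list calls below were lost with an estimated correlation, where 0 of 33 lists passed against 17 with the preset one and 9 with fry. On 4 residual degrees of freedom camera with an estimated correlation could hardly pass any list. Even cell cycle genes, of which 27 of 30 fell, had an unadjusted p of 0.0111 by it, so a loss does not show that a list was unmoved. The estimated correlation was 0.349 for the cell cycle, 0.386 for cholesterol synthesis, 0.472 for hepatocyte markers and 0.532 for the proteasome. Among the called lists only stellate markers, at -0.045, lay below the preset 0.01. Where members are correlated more than the preset value, the camera p-values below are too small.

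Cell cycle genes formed the list with the smallest p in shDnajb9. Of 30, 27 fell, 27 also when adjusted over the list alone, and 3 were not called (camera adjusted p = 1.35e-37; adjusted p = 0.365 with an estimated correlation). Their median log2 fold change was -2.52. Ccnb1, the cyclin of mitotic entry with 42.1% of its sequence shared, fell by 4.02, Tpx2 by 3.55, Cdc20 by 3.36 and Ccne1, cyclin E1, by 3.00. Targets of p53 fell in 10 of 18 genes, 11 adjusted over the list alone (camera adjusted p = 1.95e-05; adjusted p = 0.388 with an estimated correlation), among them Cdkn1a by 3.23 and Tnfrsf10b by 3.01. Of 16 NRF2 targets, 8 fell and 2, Gsta3 and Gstp1, rose, and 10 fell and 2 rose adjusted over the list alone (camera adjusted p = 2.3e-05; adjusted p = 0.366 with an estimated correlation). Abcc4 fell by 4.14, Srxn1, sulfiredoxin, by 2.51 and Slc7a11, the cystine transporter, by 5.27. Slc7a11 also belongs to the list of PERK-ATF4 and amino acid response genes, where 10 of 29 fell and 1, Cth, rose, 10 and 2 adjusted over the list alone (camera adjusted p = 0.0239; adjusted p = 0.427 with an estimated correlation). Psat1 of serine synthesis fell by 2.97, Atf3 by 2.05 and the hormone gene Fgf21 by 3.26, while Ddit3 (CHOP) was at 0.04 (adjusted p = 0.935), -0.40 with total count only, -0.05 without lacZ1 replicate 1 and -0.18 without shDnajb9 replicate 1. The camera call of this list was lost without shDnajb9 replicate 2 (adjusted p = 0.18). In the xenobiotic metabolism list 8 rose and 11 fell of 31, 8 and 14 adjusted over the list alone (camera adjusted p = 0.0457; adjusted p = 0.567 with an estimated correlation). Nqo1 fell by 2.46, Gstm3 and Gsta1, uncertain at 28.8% and 89.7% shared sequence, fell by 4.02 and 3.68, and Cyp2e1 and 4 Cyp2c genes were among the risers, where 3 rose and 16 fell by total count. This call was lost without lacZ1 replicate 2 (adjusted p = 0.0904), without shDnajb9 replicate 2 (adjusted p = 0.279), with total count only (adjusted p = 0.0543), in the 4 libraries compared alone (adjusted p = 0.173) and without genes that share sequence (adjusted p = 0.65).

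In 4 of the metabolic lists the called genes mostly rose in shDnajb9. Of 26 cholesterol synthesis genes, 16 rose, 19 adjusted over the list alone, where 1 fell (camera adjusted p = 2.05e-09; adjusted p = 0.388 with an estimated correlation). Fdps, farnesyl diphosphate synthase, rose 7.79-fold from 69.1 ± 19.3 to 538 ± 112 CPM (SD, n = 2; adjusted p = 0.000291), and Tm7sf2, Pmvk and Stard4 rose by 2.79, 1.94 and 1.75 on the log2 scale. Growth hormone dependent genes rose in 13 of 24 and fell in 1, Stat5a, with 16 and 1 adjusted over the list alone (camera adjusted p = 1.23e-09; adjusted p = 0.388 with an estimated correlation). Mup21 rose by 4.76 and Nudt7 by 2.72. Hsd3b5 rose by 6.67, with 21.2% of its sequence shared. Of 19 gluconeogenesis and FoxO1 target genes 11 rose, 12 adjusted over the list alone (camera adjusted p = 6.92e-05; adjusted p = 0.366 with an estimated correlation), among them Slc37a4, the glucose 6-phosphate transporter, by 1.69. G6pc, glucose 6-phosphatase, rose by 1.99 (adjusted p = 0.00749), a call lost without lacZ1 replicate 1 (1.83, adjusted p = 0.0972). Bile acid synthesis and transport genes rose in 10 of 22, 13 adjusted over the list alone, where 2 fell (camera adjusted p = 0.000351; adjusted p = 0.518 with an estimated correlation), with Slco1a1, an organic anion transporter, up by 4.54. By total count 11 cholesterol genes rose and 1 fell, 5 gluconeogenesis genes rose and 1 fell, and 6 bile acid genes rose and 3 fell.

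Part of the protein folding and degradation genes rose in shDnajb9. In the list of endoplasmic reticulum chaperones and XBP1/ATF6 targets 14 of 40 rose, 14 adjusted over the list alone, and none fell (camera adjusted p = 1.87e-05; adjusted p = 0.427 with an estimated correlation), while by total count 6 rose and 2 fell. Derl2 and Edem2, which act in disposal of misfolded proteins, rose by 1.62 (SE 0.284, adjusted p = 0.00197) and 1.55 (SE 0.25, adjusted p = 0.00115). Hspa5 (BiP) was at 1.01 (adjusted p = 0.0678) and Xbp1 at 0.30 (adjusted p = 0.485), which was -0.14 with total count only. Hspa5 passed with no filter (adjusted p = 0.0386), with DESeq2 (adjusted p = 0.0102), after the length and GC correction (adjusted p = 0.0385) and without shDnajb9 replicate 2 (1.26, adjusted p = 0.0427). Proteasome subunits rose in 11 of 31, 12 adjusted over the list alone (camera adjusted p = 5.05e-05; adjusted p = 0.535 with an estimated correlation), by about a doubling where called. Scaled by total count no subunit passed, and Psma7 and Psmb7, at 1.19 and 1.04, lost their calls without lacZ1 replicate 1 (0.95, adjusted p = 0.194, and 0.77, adjusted p = 0.205) and without shDnajb9 replicate 1 (0.72, adjusted p = 0.161, and 0.71, adjusted p = 0.127). The list of 24 cytosolic heat shock genes also holds Hspd1 and Hspe1, which encode mitochondrial chaperonins. Of the 24, 4 rose and 1, Hsp90aa1, fell, with the same counts adjusted over the list alone (camera adjusted p = 0.0239, and adjusted p = 0.553 with an estimated correlation). Hspe1 rose by 1.40, a call lost without lacZ1 replicate 1 (1.24, adjusted p = 0.0739), and the call of the list was lost without genes that share sequence (adjusted p = 0.0595). By total count 2 rose and 1 fell.

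Interferon response genes went both ways in shDnajb9. Of 45, 14 rose and 5 fell, 15 and 5 adjusted over the list alone (camera adjusted p = 0.0234; adjusted p = 0.518 with an estimated correlation), with a median of 0.26 that was -0.17 with total count only, where 6 rose and 6 fell. Ifit1 and Isg15, induced by type I interferon, rose 5.66-fold (adjusted p = 0.000245) and 3.99-fold (adjusted p = 0.000912). Ifit3 rose by 1.67, with 51.2% of its sequence shared. The class II antigen presentation genes H2-Aa, H2-Ab1, Cd74 and Ciita fell with Igtp, and H2-Aa fell by 2.16. The call of the list was lost without shDnajb9 replicate 2 (adjusted p = 0.0655) and in the 4 libraries compared alone (adjusted p = 0.0592).

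Markers of cell types moved with these groups in shDnajb9. Hepatocyte markers rose in 9 of 17, 11 adjusted over the list alone (camera adjusted p = 1.87e-05; adjusted p = 0.427 with an estimated correlation), with Hpd up by 2.64, and 6 rose by total count. Periportal hepatocyte markers rose in 4 and fell in 1 of 13, 8 and 2 adjusted over the list alone (camera adjusted p = 0.00796; adjusted p = 0.518 with an estimated correlation), with Hal, histidine ammonia-lyase, up by 1.94. Stellate cell and fibroblast markers fell in 10 and rose in 3 of 20, 11 and 3 adjusted over the list alone (camera adjusted p = 0.0203; adjusted p = 0.366 with an estimated correlation). Thbs1, Mmp2 and Col3a1 fell by 2.24, 1.77 and 1.52, whereas Ecm1, Colec11 and Hand2 rose, and the call of the list was lost without shDnajb9 replicate 2 (adjusted p = 0.0634). Neutrophil markers fell in 6 of 9, 8 adjusted over the list alone (camera adjusted p = 0.00252; adjusted p = 0.427 with an estimated correlation). Their raw counts summed to 619 and 213 in lacZ1 and to 33 and 154 in shDnajb9, so single genes rest on few reads. In lacZ1, replicate 1 held most counts of Ltf (124 against 14 in replicate 2), Ngp (62 against 10) and Camp (35 against 9). Mpo, with 37 counts in lacZ1 and 0 in shDnajb9, was at least 8.48-fold lower against a floor of 3 counts over the group, with 32 of the 37 counts in lacZ1 replicate 1. Its call was lost without lacZ1 replicate 1 (adjusted p = 0.242), shDnajb9 replicate 1 (adjusted p = 0.122) or shDnajb9 replicate 2 (adjusted p = 0.125). The median of the list was -3.76, or -3.08 with Mpo at that bound.

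The remaining lists were not called in shDnajb9, at camera adjusted p from 0.0565 to 0.877. Of the 32 genes of mTOR complexes and insulin signalling 3 rose and 4 fell (camera adjusted p = 0.826), and the median of 0.10, which was -0.32 with total count only (0 rose and 5 fell), and the mean of -0.12 differed in sign. Mlst8, a subunit of both mTOR complexes with 20% of its sequence shared, fell by 1.54 (SE 0.332, adjusted p = 0.00621). Mtor was at -1.78 (adjusted p = 0.0174), and its call was lost without lacZ1 replicate 1 (-1.50, adjusted p = 0.147), without shDnajb9 replicate 1 (-1.32, adjusted p = 0.151) and against a 1.5-fold change (adjusted p = 0.056). Irs2 at 1.11 (adjusted p = 0.0318), Ppargc1a at 1.03 (adjusted p = 0.0256) and Akt2 at 0.84 (adjusted p = 0.0435) passed in all 8 libraries. Irs2 lost its call without lacZ1 replicate 1 (1.52, adjusted p = 0.0523), lacZ1 replicate 2 (0.79, adjusted p = 0.193) and shDnajb9 replicate 2 (0.53, adjusted p = 0.25). Ppargc1a lost it without the same libraries (0.88, adjusted p = 0.207; 1.15, adjusted p = 0.0668; 0.50, adjusted p = 0.224), and Akt2 without lacZ1 replicate 1 (0.83, adjusted p = 0.219), lacZ1 replicate 2 (0.81, adjusted p = 0.163) and shDnajb9 replicate 1 (0.44, adjusted p = 0.327). All 3 also lost it with total count only. The rest of the panel did not pass, with log2 fold changes of 0.14 for Mapkap1, -0.68 for Rptor, 0.13 for Insr, -0.65 for Irs1 (30.5% of its sequence shared), -0.45 for Foxo1, 0.04 for Srebf1, -0.51 for Fasn, 0.55 for Scd1, 1.12 for Pck1 and 0.50 for Igfbp1. Of these, the signs of Mapkap1, Insr and Srebf1 turned with total count only, those of Insr (-0.47) and Scd1 (-0.21) without shDnajb9 replicate 2, those of Insr (-0.08) and Srebf1 (-0.31) without lacZ1 replicate 2 and that of Fasn (0.12) after the length and GC correction, and Pck1 passed with no filter, with DESeq2, in the 4 libraries compared alone and after the length and GC correction.

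Of the other lists not called, genes rose and fell in 5 and 2 of 25 for fatty acid and triglyceride synthesis (camera adjusted p = 0.0565), 3 and 2 of 23 for glycolysis and glycogen (0.0684), 1 and 7 of 34 for fatty acid oxidation (0.159) and 4 and 6 of 26 for lipid droplets and lipoproteins (0.12). The counts were 4 and 0 of 21 for the circadian clock (0.0674), 5 and 7 of 29 for acute phase proteins (0.483) and 4 and 0 of 26 for autophagy and lysosome (0.0623). Among cell types they were 5 and 2 of 16 for pericentral hepatocytes (0.136), 0 and 3 of 17 for Kupffer cells and macrophages (0.0684), 1 and 2 of 20 for T and NK cells (0.0874) and 0 and 0 of 7 for B and plasma cells (0.877). They were 2 and 0 of 17 for sinusoidal endothelium (0.123), 0 and 3 of 10 for cholangiocytes (0.0719), 2 and 2 of 6 for erythroid cells and 1 and 0 of 2 for pancreas (0.78 and 0.0623). By total count fallers outnumbered or equalled risers in autophagy (1 rose and 5 fell), glycolysis (2 and 7), fatty acid synthesis (4 and 4), pericentral markers (1 and 2) and endothelium (0 and 2). Other counts were then 1 and 12 for fatty acid oxidation, 4 and 11 for lipid droplets, 2 and 7 for acute phase proteins, 2 and 1 for the clock, 0 and 7 for macrophages, 1 and 6 for T and NK cells and 1 and 3 for erythroid cells. The medians of fatty acid synthesis, glycolysis, the clock, acute phase proteins and endothelium, all positive with TMM, were then negative (-0.10, -0.08, -0.21, -0.12 and -0.06).

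The comparison of shRictor with lacZ2 asks which transcripts differ after delivery of the hairpin against Rictor. Most cell cycle genes and p53 targets and part of the NRF2 targets fell. Of growth hormone dependent genes 16 of 24 rose, of fatty acid synthesis genes 13 of 25, of cholesterol synthesis genes 13 of 26, of gluconeogenesis genes 10 of 19, of bile acid genes 10 of 22 and of clock genes 8 of 21. With an estimated correlation 0 of 33 lists were called. Of 13767 genes, 2508 were called, 1006 that rose and 1502 that fell, and 756 and 1249 of these changed 2-fold or more. Rgs16, a regulator of G protein signalling, rose 12.5-fold from 9.95 ± 0.415 to 124 ± 8.01 CPM (SD, n = 2; adjusted p = 4.84e-05). Extl1 rose 14.3-fold (3.84, SE 0.333, adjusted p = 4.84e-05), Hcn3, a channel gene, by 4.50, Ces3b by 4.51 with 26.1% of its sequence shared, and Lrit1, P2ry4, Sntg2 and Mup1 by 2.81, 2.79, 3.50 and 5.05. Among the fallers, Ly6d went from 310 ± 160 to 7.54 ± 1.51 CPM, 40.9-fold lower (adjusted p = 3.63e-05). Cyp2a4, Cbr3, Cox6b2, Mybl1, Ckap2 and Ccne1 fell by 6.29, 5.08, 3.74, 3.65, 3.68 and 3.04 on the log2 scale.

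Here too the counts rest on the scaling and on single libraries. With total count only, where the median log2 fold change was -0.424 instead of -0.02, 436 genes rose and 2810 fell. The number called was 1062 without lacZ2 replicate 1, 1154 without shRictor replicate 1, 1320 without shRictor replicate 2 and 1120 against a 1.5-fold change. Of 33 lists 19 were called with the preset correlation and 15 with fry.

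Cell cycle genes fell in 29 of 30 in shRictor, 29 adjusted over the list alone (camera adjusted p = 2.36e-40, and adjusted p = 0.111 with an estimated correlation), with a median of -2.35. Cdk1, the mitotic kinase, fell 6.57-fold from 33.2 ± 1.24 to 5.03 ± 0.78 CPM (SD, n = 2; adjusted p = 0.000104), and Aurka and Cdc20 fell by 2.84 and 3.07 on the log2 scale. Targets of p53 fell in 13 of 18, 13 adjusted over the list alone (camera adjusted p = 1.6e-08; adjusted p = 0.152 with an estimated correlation), with Cdkn1a down by 3.66 and Phlda3 by 2.60. Of 16 NRF2 targets 9 fell, and adjusted over the list alone 9 fell and 1 rose (camera adjusted p = 1.32e-06; adjusted p = 0.152 with an estimated correlation). Srxn1 fell by 3.03 and Slc7a11 by 5.67. In the PERK-ATF4 and amino acid response list 7 of 29 fell and 1, Cth, rose, 11 and 1 adjusted over the list alone (camera adjusted p = 0.00474; adjusted p = 0.192 with an estimated correlation), with Psat1 down by 2.42, Mthfd2 by 1.86 and Fgf21 by 2.75. Here 15 fell and 1 rose by total count. Ddit3 was at -0.64 (adjusted p = 0.159) and passed with total count only (-1.05, adjusted p = 0.0298).

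In the lipid synthesis lists the called genes mostly rose in shRictor. Of 25 fatty acid and triglyceride synthesis genes 13 rose and 2, G6pdx and Pgd of the pentose phosphate pathway, fell, 16 and 2 adjusted over the list alone (camera adjusted p = 5.37e-07; adjusted p = 0.254 with an estimated correlation). Pklr, liver pyruvate kinase with 23.2% of its sequence shared, rose by 2.48 (SE 0.329, adjusted p = 0.000384), and Thrsp and Acss2 rose by 2.07 each. Srebf1, the lipogenic transcription factor, was at 1.40 (adjusted p = 0.0159), a call lost without lacZ2 replicate 1 (1.18, adjusted p = 0.123), without shRictor replicate 2 (0.98, adjusted p = 0.146), with total count only (adjusted p = 0.0546) and against a 1.5-fold change (adjusted p = 0.0663). Scd1, a desaturase, was at 2.94 (adjusted p = 0.0129), a call lost without lacZ2 replicate 1 (3.20, adjusted p = 0.0587), lacZ2 replicate 2 (2.74, adjusted p = 0.0672) and shRictor replicate 2 (1.31, adjusted p = 0.207). Fasn, fatty acid synthase, was at 1.69 (adjusted p = 0.05 after rounding) and not called, and stood at 2.34 (adjusted p = 0.0136) without shRictor replicate 1 and at 0.48 (adjusted p = 0.614) without shRictor replicate 2. It passed with RLE size factors, with no filter, with non-robust moderation, without the 10 most abundant genes, in the 4 libraries compared alone and after the length and GC correction. Scd1 was at 884 ± 204 CPM in lacZ2 against 4076 ± 381 in lacZ1 (SD, n = 2), and at 2185 and 11380 in shRictor. Fasn was at 287 ± 41.6 CPM in lacZ2 and 594 ± 197 in lacZ1. Their values in shRictor thus rest in part on a low lacZ2 level. Of 26 cholesterol synthesis genes 13 rose, 17 adjusted over the list alone (camera adjusted p = 6.84e-09; adjusted p = 0.254 with an estimated correlation), among them Tm7sf2 by 2.40, Fdps by 2.13 and Stard4 by 1.64. With total count only 7 and 6 genes of these 2 lists rose.

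Of 19 gluconeogenesis and FoxO1 target genes 10 rose, 13 adjusted over the list alone (camera adjusted p = 1.6e-08; adjusted p = 0.152 with an estimated correlation). G6pc rose by 2.45 (SE 0.452, adjusted p = 0.00276), Irs2, insulin receptor substrate 2, by 1.87 (SE 0.351, adjusted p = 0.00319) and Got1 by 1.61. Pck1, the gluconeogenic carboxykinase, was at 2.01 (adjusted p = 0.00838), a call lost without lacZ2 replicate 1 (1.67, adjusted p = 0.054) and shRictor replicate 2 (1.53, adjusted p = 0.0882). Ppargc1a, at 1.46 (adjusted p = 0.00547), lost its call without lacZ2 replicate 1 (1.27, adjusted p = 0.0742). Glycolysis and glycogen genes rose in 5 and fell in 1, Aldoa, of 23, 6 and 1 adjusted over the list alone (camera adjusted p = 0.00985; adjusted p = 0.544 with an estimated correlation), with Ppp1r3g up by 2.28. Their median of 0.22 was -0.18 with total count only, where 3 rose and 4 fell, and the call was lost without lacZ2 replicate 1 (adjusted p = 0.175). In the mTOR complexes and insulin signalling list 6 rose and 1, Prkcd, fell of 32, with the same counts adjusted over the list alone (camera adjusted p = 0.0187; adjusted p = 0.365 with an estimated correlation). The median of 0.31 was -0.10 with total count only, where 2 rose and 3 fell, and the call was lost without lacZ2 replicate 2 (adjusted p = 0.0651) and shRictor replicate 2 (adjusted p = 0.116). Deptor, an mTOR-binding protein, rose by 2.12 (SE 0.285, adjusted p = 0.000414).

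Insr was at 1.24 (adjusted p = 0.0333) and Foxo1 at 0.95 (adjusted p = 0.0316) in shRictor. Insr lost its call without lacZ2 replicate 1 (1.25, adjusted p = 0.15), lacZ2 replicate 2 (1.23, adjusted p = 0.124) and shRictor replicate 2 (0.79, adjusted p = 0.252). Foxo1 lost it without the same libraries (1.04, adjusted p = 0.122; 0.87, adjusted p = 0.153; 0.61, adjusted p = 0.262). Both lost it with total count only (0.82, adjusted p = 0.165, and 0.53, adjusted p = 0.251). The rest of the panel was not called, with log2 fold changes of 0.33 for Mapkap1, -0.37 for Mlst8, 0.11 for Mtor, 0.49 for Rptor, 0.68 for Akt2, 0.22 for Irs1, 0.19 for Igfbp1, -0.10 for Hspa5 and 0.63 for Xbp1. The signs of Mapkap1, Irs1 and Igfbp1 turned with total count only. Without shRictor replicate 2, Mtor was at -0.81, Rptor at -0.09, Irs1 at -0.35 and Igfbp1 at -0.43, against 0.67, 0.90, 0.63 and 0.62 without shRictor replicate 1. Without lacZ2 replicate 2, Mlst8 was at 0.02 and Hspa5 at 0.44, so these values carry no direction.

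Growth hormone dependent genes rose in 16 of 24 in shRictor, 19 adjusted over the list alone (camera adjusted p = 1.6e-16; adjusted p = 0.152 with an estimated correlation). Igfals, the acid-labile subunit that carries IGF1, rose by 1.72, Mup21 by 4.17 and Nudt7 by 2.39. Bile acid genes rose in 10 of 22, 14 adjusted over the list alone (camera adjusted p = 1.6e-08; adjusted p = 0.254 with an estimated correlation), with Cyp8b1, the sterol 12-alpha-hydroxylase, up by 2.93, the bile acid uptake carrier Slc10a1 by 2.89 and Slc27a5 by 2.16, and 7 rose by total count. Circadian clock genes rose in 8 of 21, 14 adjusted over the list alone (camera adjusted p = 2.54e-06; adjusted p = 0.111 with an estimated correlation). The output factors Dbp and Hlf rose by 1.60 and 1.61, where 27.5% of the Dbp sequence is shared, and 4 genes rose with total count only. Interferon response genes fell in 8 of 45, 9 adjusted over the list alone (camera adjusted p = 0.0032; adjusted p = 0.365 with an estimated correlation). H2-Aa fell by 1.87, and by 1.24 without lacZ2 replicate 2, and Mx1 was at -1.31 (adjusted p = 0.00692), a call lost without shRictor replicate 1 (-1.19, adjusted p = 0.0671). By total count 23 fell, and the call of the list was lost without lacZ2 replicate 2 (adjusted p = 0.13).

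Cell type markers in shRictor moved as follows. Hepatocyte markers rose in 7 of 17, 13 adjusted over the list alone (camera adjusted p = 1.6e-08; adjusted p = 0.254 with an estimated correlation), with Hpd up by 2.66. Periportal markers rose in 8 of 13, 9 adjusted over the list alone (camera adjusted p = 2.11e-06; adjusted p = 0.254 with an estimated correlation), with Pigr, Hal and Gls2 up by 2.48, 2.47 and 2.08, and 6 rose and 2 fell by total count. Pericentral markers rose in 7 and fell in 1 of 16, 10 and 1 adjusted over the list alone (camera adjusted p = 0.000101; adjusted p = 0.365 with an estimated correlation), with Rgn up by 1.99 and the amino acid transporter Slc1a4 down by 3.99. Under total count scaling 2 pericentral markers rose and 2 fell. Stellate cell and fibroblast markers fell in 7 and rose in 1, Ecm1, of 20, 11 and 2 adjusted over the list alone (camera adjusted p = 0.00715; adjusted p = 0.157 with an estimated correlation). Col5a2 and Col3a1 fell by 1.95 and 1.60, and by total count 12 fell and 1 rose. Kupffer cell and macrophage markers fell in 6 of 17, 10 adjusted over the list alone (camera adjusted p = 0.00458; adjusted p = 0.457 with an estimated correlation), 11 by total count, a call lost without lacZ2 replicate 2 (adjusted p = 0.0651). Cd68 was at -0.97 (adjusted p = 0.00937), a call lost without shRictor replicate 1 (adjusted p = 0.0701) and shRictor replicate 2 (adjusted p = 0.0624). T and NK cell markers fell in 3 of 20, Gzma, Cd8a and Gzmb, 7 by total count and 5 adjusted over the list alone (camera adjusted p = 0.0202; adjusted p = 0.544 with an estimated correlation), a call lost without lacZ2 replicate 2 (adjusted p = 0.565), without shRictor replicate 2 (adjusted p = 0.102), with total count only (adjusted p = 0.0989) and after the length and GC correction (adjusted p = 0.0545).

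Of the lists not called in shRictor, genes rose and fell in 2 and 2 of 40 for endoplasmic reticulum chaperones and XBP1/ATF6 targets (camera adjusted p = 0.159), 0 and 1 of 24 for cytosolic heat shock proteins (0.383), 0 and 0 of 31 for the proteasome (0.887), 6 and 9 of 31 for xenobiotic metabolism (0.676) and 1 and 4 of 34 for fatty acid oxidation (0.668). The counts were 3 and 4 of 26 for lipid droplets (0.846), 4 and 3 of 29 for acute phase proteins (0.161) and 4 and 0 of 26 for autophagy (0.0996). They were 0 and 1 of 7 for B and plasma cells (0.161), 0 and 1 of 9 for neutrophils (0.0786), 1 and 0 of 17 for sinusoidal endothelium (0.45), 0 and 3 of 10 for cholangiocytes (0.167), 2 and 2 of 6 for erythroid cells (0.786) and 0 and 0 of 2 for pancreas (0.208). Median, mean and test differed in sign for xenobiotic metabolism (0.41, -0.20, down), fatty acid oxidation (0.21, -0.04, up), lipid droplets (0.17, -0.09, down) and the proteasome (-0.01, -0.03, up). By total count no autophagy gene rose and 2 fell, and counts were 0 and 4 for endoplasmic reticulum chaperones, 0 and 4 for the proteasome, 0 and 7 for fatty acid oxidation, 2 and 7 for lipid droplets, 1 and 4 for acute phase proteins, 5 and 11 for xenobiotic metabolism and 0 and 0 for endothelium. The medians of fatty acid oxidation, lipid droplets, endoplasmic reticulum chaperones, heat shock proteins, acute phase proteins, autophagy and endothelium, all positive with TMM, were then negative (-0.18, -0.23, -0.25, -0.20, -0.12, -0.24 and -0.28).

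**Figure D2:**
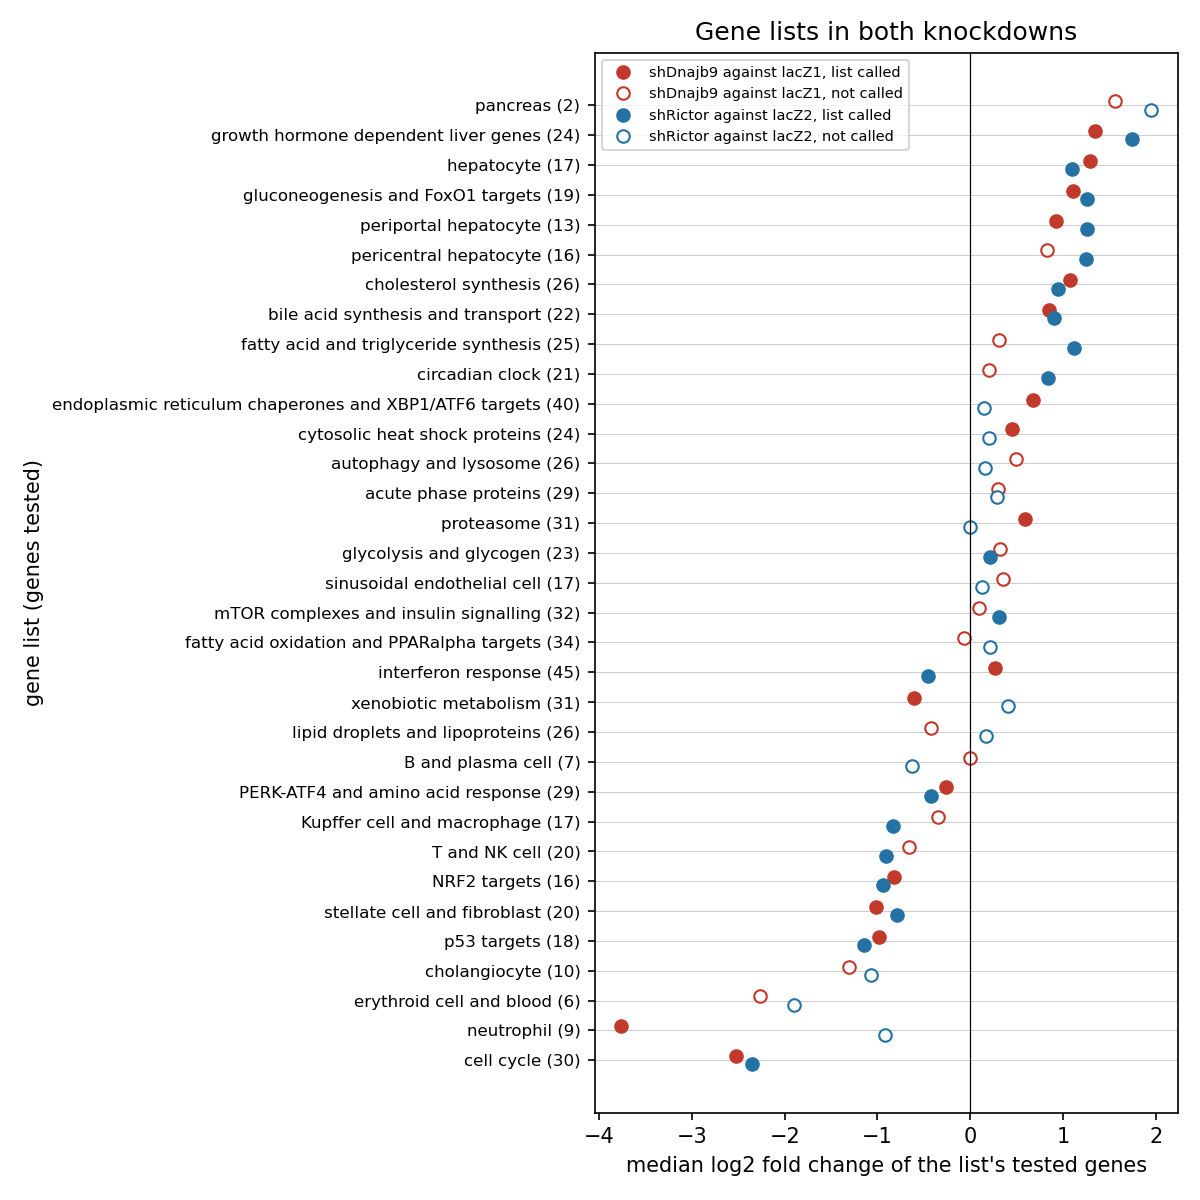
Median log2 fold change of the tested genes of each list (number tested in brackets) in shDnajb9 against lacZ1 (red) and in shRictor against lacZ2 (blue), with filled points for lists called by camera at the preset correlation. Cell cycle genes stood at -2.52 and -2.35, and growth hormone dependent genes at 1.35 and 1.74, and 0 lists of either knockdown were called with an estimated correlation.

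Whether both knockdowns moved the same genes was asked with the overlap of the called genes. The shared risers numbered 573, where 117 would be shared by chance (Fisher's exact test, one-sided, p = 4.3e-301), and the shared fallers numbered 943, where 189 would be shared by chance (p below the smallest number the software can hold). These tests treat genes as independent, which they are not. Extl1, Mup1, Sntg2, P2ry4 and Car5a led the shared risers and Cyp2a4, Ly6d, Cbr3, Ccne1 and Cox6b2 the shared fallers. P2ry4 rose by 2.51 in shDnajb9 and 2.79 in shRictor, and Car5a, a mitochondrial carbonic anhydrase with 22.4% of its sequence shared, by 2.27 and 2.32. Across all genes the fold changes of both contrasts had Pearson's r = 0.738 and Spearman's rho = 0.646, and no control library was shared. The value of r was 0.445 with no filter. Genes called in both numbered 1524, of which 8 went in opposite directions.

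**Figure D3:**
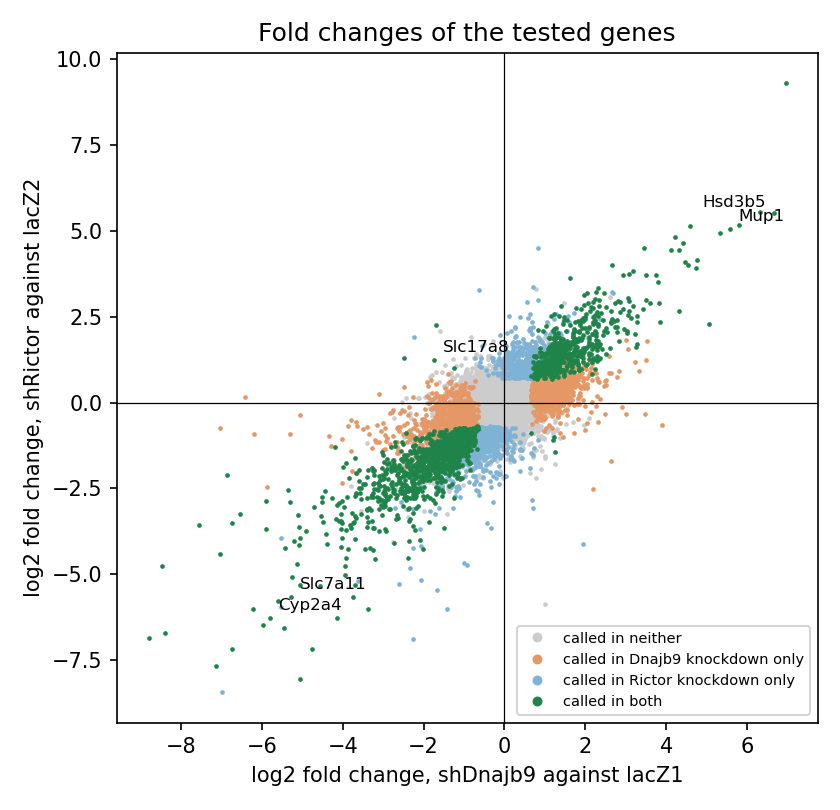
Log2 fold change of each of 13767 genes in shDnajb9 against lacZ1 (horizontal axis) and in shRictor against lacZ2 (vertical axis), coloured by the knockdown in which the gene was called. The genes lie along a rising diagonal (r = 0.738 over all 13767 genes), and Slc17a8 lies off it at -1.73 and 1.23.

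The difference between the knockdowns, tested as an interaction, singled out Slc17a8, which encodes a vesicular glutamate transporter (chromosome 10, 89574020 to 89621253). It fell from 33.0 ± 2.85 to 9.90 ± 0.367 CPM in shDnajb9 and rose from 35.6 ± 5.5 to 83.9 ± 6.43 CPM in shRictor (SD, n = 2). The difference was 2.97 on the log2 scale (SE 0.332, adjusted p = 0.0085), and both single effects were called, at -1.73 (adjusted p = 0.000469) and 1.23 (adjusted p = 0.00252). The call of the difference was lost without lacZ1 replicate 2 (2.89, adjusted p = 0.0686), lacZ2 replicate 1 (2.83, adjusted p = 0.163) and shRictor replicate 2 (2.89, adjusted p = 0.0511), and without the 2 libraries that stood apart (2.79, adjusted p = 0.193). For the other 7 genes called in opposite directions the difference did not pass (adjusted p from 0.122 to 0.215). With edgeR 1 gene was called for the difference, 1495 had an unadjusted p under 0.05, DESeq2 called 45 and an unfiltered fit 395. Without shDnajb9 replicate 2 there were 17, without lacZ2 replicate 2 there were 5, without shRictor replicate 1 there were 2, and none remained without lacZ1 replicate 2, lacZ2 replicate 1 or shRictor replicate 2.

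Among the lists, 13 were called in the difference with the preset correlation, 0 with an estimated one and 0 with fry. Interferon response genes were lower in shRictor relative to shDnajb9 (median difference -0.72, camera adjusted p = 2.11e-13; adjusted p = 0.441 with an estimated correlation), and 20 of 45 passed adjusted over the list alone, against 0 over all genes. The median difference of this list was -0.40 without lacZ2 replicate 2 and -0.95 without shRictor replicate 2. Isg15 stood at 2.00 in shDnajb9 and at -0.80 in shRictor on the log2 scale. The proteasome and endoplasmic reticulum lists were lower in the same sense, with medians of -0.71 and -0.66 (camera adjusted p = 3.95e-08 and 5.8e-05; adjusted p = 0.823 with an estimated correlation for both), and 0 and 7 genes passed adjusted over the list alone. Fatty acid and triglyceride synthesis was higher, with a median of 0.58 (camera adjusted p = 0.001; adjusted p = 0.823 with an estimated correlation).

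The comparison of lacZ2 with lacZ1 shows how far the 2 experiments differ, in which age and experiment cannot be told apart. With edgeR 0 of 13767 genes were called, 169 had an unadjusted p under 0.05, and the smallest adjusted p was 0.607. Of the panel, Scd1, Fasn and Pck1 were 4.61-fold, 2.07-fold and 2.07-fold lower in lacZ2 without passing. Their differences between the knockdowns therefore rest in part on the controls. DESeq2 called 1 gene, the 4 control libraries alone gave 1, an unfiltered fit 13 and a fit without lacZ2 replicate 2 gave 1. With 2 libraries per group, changes of 2-fold were recovered in 32.8% and 34.3% of simulated genes in the knockdown contrasts. Only 200 genes per knockdown were changed there. In the measured contrasts 3325 and 2508 genes were called, which eases the adjusted threshold, so this recovery does not describe them. Differences between the controls were not simulated, so the power of their comparison is not known.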

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

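The tests of shared sequence and of a length and GC trend behind the interferon difference were planned before their result was seen, and all other tests of explanations in this part were chosen after it. The bound for a single library was tightened after its value was seen. Bootstrap standard errors, and the spreads given for marker lists, come from resampling the genes of a list 2000 times. They measure the spread between genes, which are not independent, and not that between libraries.

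Slc17a8 was singled out because its response differed between the knockdowns by 2.97 on the log2 scale in the interaction test, and no explanation was tested. The lists below were singled out because their members' responses differed as a set by camera at the preset correlation, and none did so with an estimated correlation. Median differences, Rictor minus Dnajb9 knockdown, were 0.25 for mTOR complexes and insulin signalling, 0.58 for fatty acid and triglyceride synthesis, 0.36 for fatty acid oxidation, -0.66 for endoplasmic reticulum chaperones, -0.24 for cytosolic heat shock proteins, -0.71 for the proteasome and 0.31 for bile acid genes. They were 0.32 for xenobiotic metabolism, 0.34 for the circadian clock, -0.72 for the interferon response, 0.26 for pericentral and 0.49 for periportal hepatocytes and 1.77 for neutrophils. Outside the gene counts, reads without a unique alignment stood above both libraries of the own control in shDnajb9 (mean 41.6%) and in shRictor (mean 29.7%). Reads that overlapped several genes stood above both lacZ1 libraries in shDnajb9 (mean 1.14%), but not above lacZ2 replicate 2 (1.15%).

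Both knockdowns moved the same genes against separate lacZ controls. A length or GC trend as the whole cause was argued against by the correlation of the fold changes, 0.773 after the correction. A lower share of all non-hepatocyte cells cannot be told apart. Endothelial markers lay above stellate markers by 1.37 (bootstrap SE 0.443) in shDnajb9 and 0.924 (bootstrap SE 0.327) in shRictor. The endothelial markers did not fall with TMM, with medians of 0.355 and 0.13. With total count only their medians were -0.06 and -0.28. The sign of the endothelial medians thus depends on the scaling, and marker levels can change within a cell type, so these values do not decide. A change in a single cell type stays open too. A difference between the lacZ virus and the targeting viruses as such cannot be told apart from a shared effect of the knockdowns. Of the genes called in both, 99.5% moved the same way, and no uninfected liver or control named as a hairpin was in the series. The labels do not say whether the lacZ virus was itself a hairpin control. A biological link between Dnajb9 and mTOR complex 2 stays open and untested.

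The larger share of reads without a unique alignment in shDnajb9 was weighed against ribosomal RNA and gene families. The Rn45s share of gene counts in shDnajb9 was 1.1 times that in lacZ1 (spread 0.33), and genes that share sequence took 1.13 times the share (spread 0.0776). Neither decides, since reads that align to several places are not in these counts, so both explanations stay open. The knockdown itself was not tested as a cause.

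Interferon response genes were lower in shRictor than in shDnajb9, each taken against its own control. A length or GC trend was argued against, since the median difference was -0.60 after the correction and the list kept its camera call (adjusted p = 3.79e-14). A single library cannot be told apart, since the median difference without lacZ2 replicate 2 was -0.403 (bootstrap SE 0.309), and up to -0.951 without shRictor replicate 2. Fewer immune cells cannot be told apart either, as markers of T and NK cells lay 0.622 (spread 0.291) and of macrophages 0.387 (spread 0.265) above the interferon list. Age differs between the experiments and stays open, as does an effect of the targeted genes.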

How the results depend on the processing

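The length and GC correction, the fit without shDnajb9 replicate 1 and lacZ2 replicate 1, the fit without genes that share sequence and the crossed block were chosen after seeing the data. Genes called in the Dnajb9 knockdown (3325) were 2184 with a replicate block, 1314 against a 1.5-fold change, 1678 without those 2 libraries, and 988 (without lacZ1 replicate 1) to 4157 (without shDnajb9 replicate 2) with 1 library left out. For Rictor (2508) they were 1120 against a 1.5-fold change and 1062 (without lacZ2 replicate 1) to 1955 (without lacZ2 replicate 2). For the difference (1) they were 395 with no filter, 45 with DESeq2, 233 with the crossed block, 0 with the replicate block and without those 2 libraries, and 0 (without lacZ1 replicate 2) to 17 (without shDnajb9 replicate 2). Slc17a8 was at 2.98 (adjusted p = 0.0771, edgeR) with the replicate block. For lacZ2 against lacZ1 (0 with edgeR, 169 at an unadjusted p under 0.05) they were 13 with no filter, 1 in the 4 libraries compared, 1 with DESeq2, and 0 to 1 (without lacZ2 replicate 2). The Dnajb9 transcript passed with total count only (-1.12), no filter (-0.71) and the length and GC correction (-1.06), and Rictor was at -0.92 with total count only. The correlation of both contrasts was 0.445 with no filter and 0.615 (without shDnajb9 replicate 2) to 0.778 (without shRictor replicate 2). Lists called fell from 17 to 0 with an estimated correlation and 9 with fry for Dnajb9. For Rictor they fell from 19 to 0 with an estimated correlation and 15 with fry. Fewer libraries or a stricter hypothesis explain lower counts by construction, and otherwise the cause was not tested. Of 3703 alternatives for 218 named gene results, 3369 kept their side of the threshold without a marked shift, 250 lost the call, 24 gained it and 60 not called moved. Most of these genes were named for a small p, and 189 of the 218 results were called, so this tally does not describe all genes. No called value changed sign, while values not called did so in 33 alternatives. Depth was 6426164 to 11383532 gene counts per library, which limits genes with few reads such as the neutrophil markers.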

Other observations

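The test in this part was chosen only after the rise of growth hormone dependent genes was seen.

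Many growth hormone dependent liver genes differ between the sexes, and the labels give no sex. A candidate explanation for their rise is a shift of sex-biased genes toward the male-biased pattern. Of 20 listed male-biased genes 14 rose in each knockdown, with medians of 2.05 and 2.01, but this list shares members with the growth hormone list. Female-biased genes, of which 11 of 20 were tested, had medians of -1.50 (bootstrap SE 0.767) in shDnajb9 and -1.28 (bootstrap SE 0.874) in shRictor, against -0.05 and -0.02 for all genes. In shDnajb9 3 fell and 0 rose, and in shRictor 5 fell and 3, Fmo2, Cyp2c40 and Cyp2c69, rose. The spread leaves the hypothesis open. Animals of different sex in the groups were not excluded, since transcripts of the sex chromosomes were not examined for the sex of the animals.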
